A study of Mus musculus with 8 samples.

How the data were processed

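The samples were 6 RNA-seq libraries of mouse embryonic stem cells (R1 and R1/E) in embryoid body culture, control and doxycycline-induced Oct6 at days 2, 4 and 6, and at day 4 an Oct6 ChIP library and an input library. The labels give the cells of the ChIP and of the input as overexpressing Oct6. Groups and days were taken from the sample labels. The library titles carry a prefix, fbs, that the labels do not explain, and the growth protocol describes serum-free differentiation, so the medium of these libraries is left open. The titles name doxycycline only for the induced libraries, and the labels do not say whether control cells received it. If they did not, an effect of doxycycline itself cannot be told apart from one of Oct6. The labels also do not say whether control and induced cells are of the same line. If they are not, a difference between lines cannot be told apart from an effect of Oct6 either.

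Per the submitters' processing notes, TopHat 1.4.1, Cufflinks 1.3.0, Cuffdiff and HOMER were used with the mouse genome build mm9. The deposited FPKM values, fragment numbers scaled to transcript length and to the mapped fragments of the library, come as 1 table of gene symbols by library, made by the authors. How multi-mapping reads were treated, and whether libraries were strand-specific, is not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense partners are uncertain. The peak list gives for each peak a position and a score, both the authors' deposited values. The peak scores were used only to rank and describe peaks within that list, and the ChIP and input signal itself was not analysed here. Peaks ended within the chromosome lengths of the NCBIM37 reference, the assembly behind mm9, whose GENCODE annotation gave gene positions. Of the table's symbols 95.7% matched an annotation symbol, and 98.1% of the expressed ones did. Peaks on unplaced contigs (14) were left out of position and motif counts. Current symbols for older ones came from RefSeq synonyms.

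Values were taken as log2(FPKM + 1), so folds of weakly expressed genes are understated. A gene counted as changed between 2 libraries when its FPKM was at least 1 in either and the log2 values differed by at least 1. With 1 library per arm and day no test was made within a day. An exact 0 can be a failed estimate: 24 genes were listed at 0 in some library and at 10 FPKM or more in another, 14 of them small RNA, predicted or pseudogene symbols, and such genes are described as listed at 0. For relative depth, log2 ratios of genes below 0.3 FPKM were compared with control day 2 and the most frequent ratio taken as the ratio of what 1 fragment is worth. In the other 5 libraries that step held 199 to 342 genes, against a median of 17 to 30 for other ratios. The estimated fragment numbers rest on annotated transcript lengths and are estimates.

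Differences common to the 3 days were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, day as a block, 2 residual degrees of freedom, Benjamini-Hochberg adjustment) on genes with an FPKM of 1 or more in at least 1 library. A second fit with the interaction of arm and numeric day tested a day trend. What is tested is the spread of the effect between days, not between repeated cultures. For 25 gene lists fixed before the data were examined, the median difference per day was set against 10000 random lists in which each member was replaced by 1 of the 100 expressed genes nearest in mean log2 value. None of the lists holds Pou3f1. limma's camera was run with the preset correlation of 0.01 and with an estimated one, and fry beside it. fry asks whether a list's genes move on balance in 1 direction and compares no list with other genes.

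Named genes followed a rule set before the data were examined: Pou3f1; the 8 largest mean differences in each direction among genes at least 2-fold changed in the same direction on all 3 days; the 4 largest differences in each direction on each day and in control from day 2 to day 6; up to 4 members per list with the largest difference on any day; a fixed set of neural, pluripotency, germ layer, BMP and Wnt genes; and the 10 peaks of highest score. A few genes with a near peak, and genes listed with a peak within a list, were named after their values were seen. A few genes that the rule takes are not reported here.

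Start sites were the annotated 5' ends of genes, and a peak within 10 kb was counted by its centre. Shares carry 95% Wilson intervals, which cover counting error only. Flanks for motif counts were sequences of the peak width whose outer end lay 500 bp from each peak edge, and 10 random positions per peak were drawn on its chromosome. Peak classes used protein-coding gene models. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

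The steps were tested on simulated data. With 200 planted genes, limma's test over the 3 days recovered 40% of those changed by 1 on the log2 scale, 84% at 2, 92% at 3 and 88% at 4, among 13661 genes, with 6 of 13461 unchanged genes passing. These changes were equal on the 3 days and planted in random genes with a mean log2 value above 2. Recovery can be lower for genes whose effect varies more between days. The day trend test recovered 0% at 1, 68% at 2, 86% at 3 and 92% at 4 (change at the last day against day 4), with 4 unchanged genes passing. The 2-fold count recovered 100% of 200 genes planted at 4-fold among 11881 genes. These changes were planted without noise in well expressed genes, so that this recovery was fixed in advance and checks only the counting. A list shifted by 1 reached percentile 100, and 7% of unshifted lists fell outside the central 95% of random lists. The unshifted lists held random genes, so the 7% does not cover lists whose members move together. For genes with a peak, a planted share of 40.5% reached percentile 100 and 4% of random sets fell outside the central 95%.

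Alternatives tried were a pseudocount of 0.1, no floor or a floor of 5 FPKM, median ratio scaling, quantile normalisation, 1.5-fold and 4-fold limits, no day block, eBayes without trend, each day left out, the 3989 peaks of highest score (ties taken in chromosome order), and windows of 2 and 50 kb. Counts without small RNA, predicted and pseudogene symbols, and named genes under median ratio scaling, were added after the data were seen.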

Results

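Oct6, the protein of the gene Pou3f1, is a POU domain transcription factor of the epiblast and of the developing nervous system. Mouse embryonic stem cells of the R1 and R1/E lines were differentiated as embryoid bodies, floating aggregates that form derivatives of all germ layers. A control culture was set beside cells in which doxycycline switched on an Oct6 transgene. Library titles name doxycycline only for the induced arm, so its own effect may be part of each difference. So may a difference between cell lines, since the labels do not say whether the arms share a line. RNA was sequenced at day 2, day 4 and day 6 in both arms, with 1 library per arm and day, which makes 6 RNA-seq libraries. In cells labelled as overexpressing Oct6, chromatin bound by Oct6 was precipitated at day 4 and sequenced as 1 ChIP library beside 1 input library. No comparison within a day therefore has a replicate check. The deposited FPKM values fall on steps worth 1 fragment in weakly expressed genes, from which relative depth was read. With control day 2 set to 1, it was 0.793 for induced day 2, 1.49 for control day 4, 0.755 for induced day 4, 0.776 for control day 6 and 0.688 for induced day 6. With annotated transcript lengths these steps correspond to an estimated 23200000 to 50700000 fragments per library. At that depth 1 fragment in a gene of 2 kb is worth an FPKM between 0.00986 and 0.0216, and genes were counted from an FPKM of 1. Of 22558 genes in the table, 13661 reached an FPKM of 1 in at least 1 library.

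Pou3f1 itself was higher in the induced library on each day. Its FPKM was 64.3 in control and 312 in induced cells at day 2, 10.1 and 222 at day 4, and 4.76 and 86.8 at day 6. The differences of log2(FPKM + 1) were 2.26, 4.33 and 3.93. In control cells the gene was most abundant at day 2. The values do not separate transcripts of the transgene from those of the gene on chromosome 4 (124334896 to 124337899, plus strand, mm9).

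**Figure D1:**
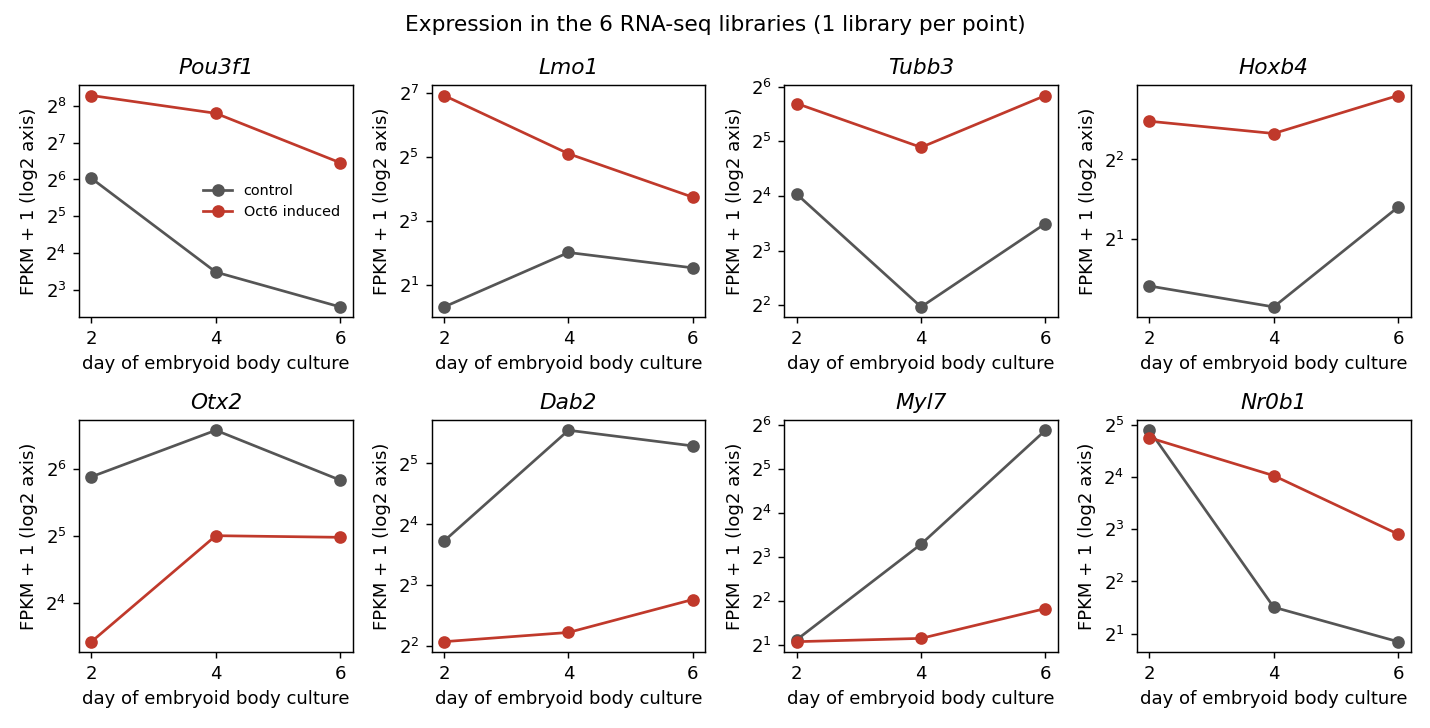
FPKM + 1 on a log2 axis against the day of culture for 8 genes, with grey points and lines for control and red for Oct6 induced cells and 1 library behind each point. Pou3f1, Lmo1, Tubb3 and Hoxb4 lay above control on all 3 days, Otx2 and Dab2 below it, Myl7 below it from day 4, and Nr0b1 above it from day 4.

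The question of the first comparison was which transcripts differ between induced and control cells on each day. At day 2, 1223 genes were at least 2-fold higher and 230 at least 2-fold lower in induced cells, among 12586 genes with an FPKM of 1 or more in either library. At day 4 the numbers were 772 higher and 268 lower, and at day 6 they were 432 higher and 269 lower. Libraries of the same arm on neighbouring days differed on a like scale. Control day 4 against day 2 gave 1186 higher and 572 lower genes, control day 6 against day 4 gave 775 and 375, induced day 4 against day 2 gave 350 and 302, and induced day 6 against day 4 gave 383 and 270. Higher genes made up 84.2% of the changed genes at day 2, 74.2% at day 4 and 61.6% at day 6. The share depends on scaling: it was 75.2% at day 2 after the libraries were scaled to a common median ratio and 61.1% after quantile normalisation, which also gave 58.5% at day 4 and 51.4% at day 6. The median difference over all expressed genes, against which the values below can be read, was 0.16 at day 2, 0.10 at day 4 and 0.06 at day 6.

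A set of 141 genes was at least 2-fold higher on all 3 days and 10 were at least 2-fold lower, where independent days would give 2.19 and 0.0888. Those numbers take every gene as equally likely to change. Genes that vary more, or any lasting difference between the arms, would exceed them, so the excess does not single out Oct6. Among the 8 leading higher genes were Scin, an actin-severing protein, with 15.2, 61.7 and 12.1 FPKM in induced cells at days 2, 4 and 6 against 0.686, 0.704 and 0.103 in control, and Lmo1, a LIM-only transcriptional cofactor, with 120, 33.3 and 12.4 against 0.244, 3.04 and 1.90. Cited4, a CBP/p300-interacting cofactor, had 51.3, 33.3 and 11.6 FPKM against 0.226, 0.0995 and 4.0. C1ql2, a secreted C1q-like protein, had 25.2, 23.8 and 4.52 against 0.0135, 0.0340 and 0.391. Ebf3, a factor of neuronal differentiation, had 37.3, 8.82 and 6.20 against 0.0981, 0.0424 and 0.661. Insm1, a zinc finger factor of neuronal and endocrine progenitors, had 59.7, 8.12 and 5.69 against 1.0, 0.0785 and 0.294. The remaining leading gene beside Pou3f1 was the non-coding 2610203C20Rik, now Mir100hg, with 13.6, 14.1 and 13.1 against 0.463, 0.118 and 0.285. The lower genes were led by Snord70, a small nucleolar RNA listed at 0 in all 3 induced libraries. Such short transcripts are poorly measured by FPKM and the value is uncertain. It was followed by Cubn and Lrp2, endocytic receptors of the visceral endoderm, with mean log2 differences of -2.67 and -2.62, and by their adaptor Dab2 at -2.50. Srgn, a proteoglycan core protein, stood at -2.42, the carbonic anhydrase Car4 at -2.01, the peptidase Dpp4 at -1.72 and the hyaluronan synthase Has2 at -1.53.

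Single-day extremes included further genes of interest and several of doubtful measurement. Shisa3, an antagonist of Wnt and FGF receptor maturation, had 62.3 FPKM in induced and 0.837 in control cells at day 2, and Nmu, a neuropeptide gene, had 29.8 at day 4 and was listed at 0 in control. The non-coding 2610017I09Rik, now Pantr1, which lies beside Pou3f3, had 18.8 against 0.0740 FPKM at day 6. Ttr, a thyroid hormone carrier of visceral endoderm, had 0.200 against 26.6 FPKM at day 4, and Afp, the fetal albumin of the same tissue, had 0.115 against 53.3 at day 6. Gm9846, Gm4535, Amd1 and Atp6v0c-ps2 share sequence with close copies, and Snord19, Snord58b, Snord110 and AF357355 are short RNAs, so that their values on these days are uncertain. Gm9846, for example, was listed at 4.58 and 1594 FPKM in the control and induced libraries of day 4.

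Of 20 measured members of the fixed neuron list, 9 were at least 2-fold higher at day 2, 7 at day 4 and 17 at day 6, where 1 was 2-fold lower, and the list medians of 0.83, 0.84 and 1.34 lay at percentile 100 among 10000 matched random lists each time. Tubb3, the neuronal beta tubulin, had 50.7, 28.6 and 56.2 FPKM against 15.4, 2.92 and 10.3. Dcx, a microtubule protein of migrating neurons, had 0.719, 3.43 and 8.68 against 0.0438, 0.0494 and 0.132. Ncam1, the neural cell adhesion molecule, had 8.82, 4.18 and 5.74 against 0.497, 0.590 and 2.25. The bHLH factor Nhlh1 had 6.16, 1.49 and 3.55, and was listed at 0 in control at days 2 and 4. Neurog2, a proneural bHLH factor, differed by 1.08 at day 6. In limma's day-blocked fit 15 of the 20 members passed as higher when adjusted over the list alone, and 0 when adjusted over all genes. The camera test of the list gave an adjusted p of 6.9e-08, and an adjusted p of 0.350 with an estimated correlation.

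The neural progenitor list, which does not hold Pou3f1, had medians of 0.48, 1.12 and 0.32, at percentiles 96.2, 100 and 99.4. Of its 20 measured members, 6, 10 and 4 were at least 2-fold higher on the 3 days, and 0, 0 and 2 at least 2-fold lower. Sox21, a SOXB2 factor, had 22.6 against 0.0853 FPKM at day 2 and 9.64 against 0.422 at day 4. Irx3, a factor of the caudal neural tube, had 17.3 against 0.655 at day 2 but 12.8 against 18.1 at day 6. Fabp7, a fatty acid binding protein of radial glia, had 58.2 against 2.31 at day 6, and Nkx6-1, a ventral neural tube factor, had 5.92 against 0.0490 at day 4. Pax6 differed by 0.77, 1.92 and 0.97 and Zic1 by 0.21, 2.24 and 2.27. Sox1, the early neuroectoderm marker, had 2.61 against 0.0307 FPKM at day 4, but 0.909 against 0.536 at day 2 and 2.31 against 1.64 at day 6. Zfp521, an activator of early neural genes, differed by 0.65 at day 4, while Sox3 differed by -0.24, -0.01 and 0.17. Zic2 was lower, with -0.67, -0.78 and -0.18, and Nes, the neural intermediate filament, varied between -0.53 and 0.86. Adjusted over the list alone, limma passed 8 members as higher and 1, Zic2, as lower, against 0 over all genes. The camera test of the list gave an adjusted p of 0.0573, and 0.429 with an estimated correlation. It passed under median ratio scaling (0.00879) and after quantile normalisation (0.0127).

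Of 13 measured Hox and Cdx genes, the factors of posterior identity, 5 were at least 2-fold higher at day 2, 6 at day 4 and 7 at day 6, and none was 2-fold lower. The medians were 0.77, 0.81 and 1.05. Hoxb4 had 4.59, 4.02 and 6.01 FPKM against 0.320, 0.0989 and 1.63, Hoxb2 had 3.46, 7.76 and 15.02 against 0.723, 0.927 and 5.67, and Hoxb8 had 0.963, 4.56 and 8.82 against 0.316, 0.0185 and 1.39. Hoxb9 reached 3.85 against 0.367 at day 6. Adjusted over the list alone, 8 members passed limma's test as higher, against 0 over all genes. The camera test gave an adjusted p of 1.15e-05, and an adjusted p of 0.350 with an estimated correlation. In the neural crest list of 8 measured members, Pax3 differed by 1.98, Tcfap2b (Tfap2b) by 1.76 and Tcfap2a (Tfap2a) by 1.41 at day 6, while Twist1 differed by 2.11 at day 2 and by -0.63 at day 6. The list medians were 0.41, 0.62 and -0.28, while the mean at day 6 was 0.36. Adjusted over the list alone, Pax3 and Tcfap2a passed limma's test as higher, against 0 over all genes.

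Medians over the 16 members of the naive pluripotency list were -0.05, 1.39 and 0.93, and 2, 10 and 7 members were at least 2-fold higher, against 3, 0 and 0 at least 2-fold lower. The camera test over the 3 days gave an adjusted p of 0.00305, and an adjusted p of 0.516 with an estimated correlation. Nr0b1 (Dax1) had 25.9 against 28.7 FPKM at day 2, 15.3 against 1.84 at day 4 and 6.50 against 0.800 at day 6. Gbx2 had 9.28 against 0.483, Nr5a2 had 12.9 against 1.38 and Dppa3 had 10.5 against 2.0 at day 4. Nanog had log2 differences of 0.07, 0.24 and 0.73, the first of which turned to -0.09 under median ratio scaling. General pluripotency genes had medians of -0.92, -0.28 and 0.21. At day 2, Pou5f1, the gene of Oct4, had 436 against 890.0 FPKM, Sox2 had 66.7 against 135, Utf1 had 100.2 against 320.3 and Tdgf1, the Nodal co-receptor Cripto, had 140.1 against 412. At day 6 Pou5f1 had 138 against 136, a difference of 0.02 that became -0.04 under median ratio scaling. Dppa4 differed by -0.48, 1.23 and 1.15. The primed epiblast list had medians of -0.98, -0.77 and -0.51, each at percentile 0. Of its 10 members 5, 4 and 0 were at least 2-fold lower, and 1 was 2-fold higher at day 2. The camera test gave an adjusted p of 3.05e-05, and an adjusted p of 0.350 with an estimated correlation. Otx2 had 9.67 against 58.0, 31.02 against 94.6 and 30.5 against 56.0 FPKM. Dnmt3b, a de novo DNA methyltransferase, had 92.7 against 348, 89.4 against 248 and 56.8 against 88.9. Foxd3 differed by -2.50, -1.11 and -0.53 and Fgf5 by -0.73, -1.41 and -0.57. Adjusted over the list alone, 6 of its 10 members passed limma's test as lower, against 0 over all genes.

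**Figure D2:**
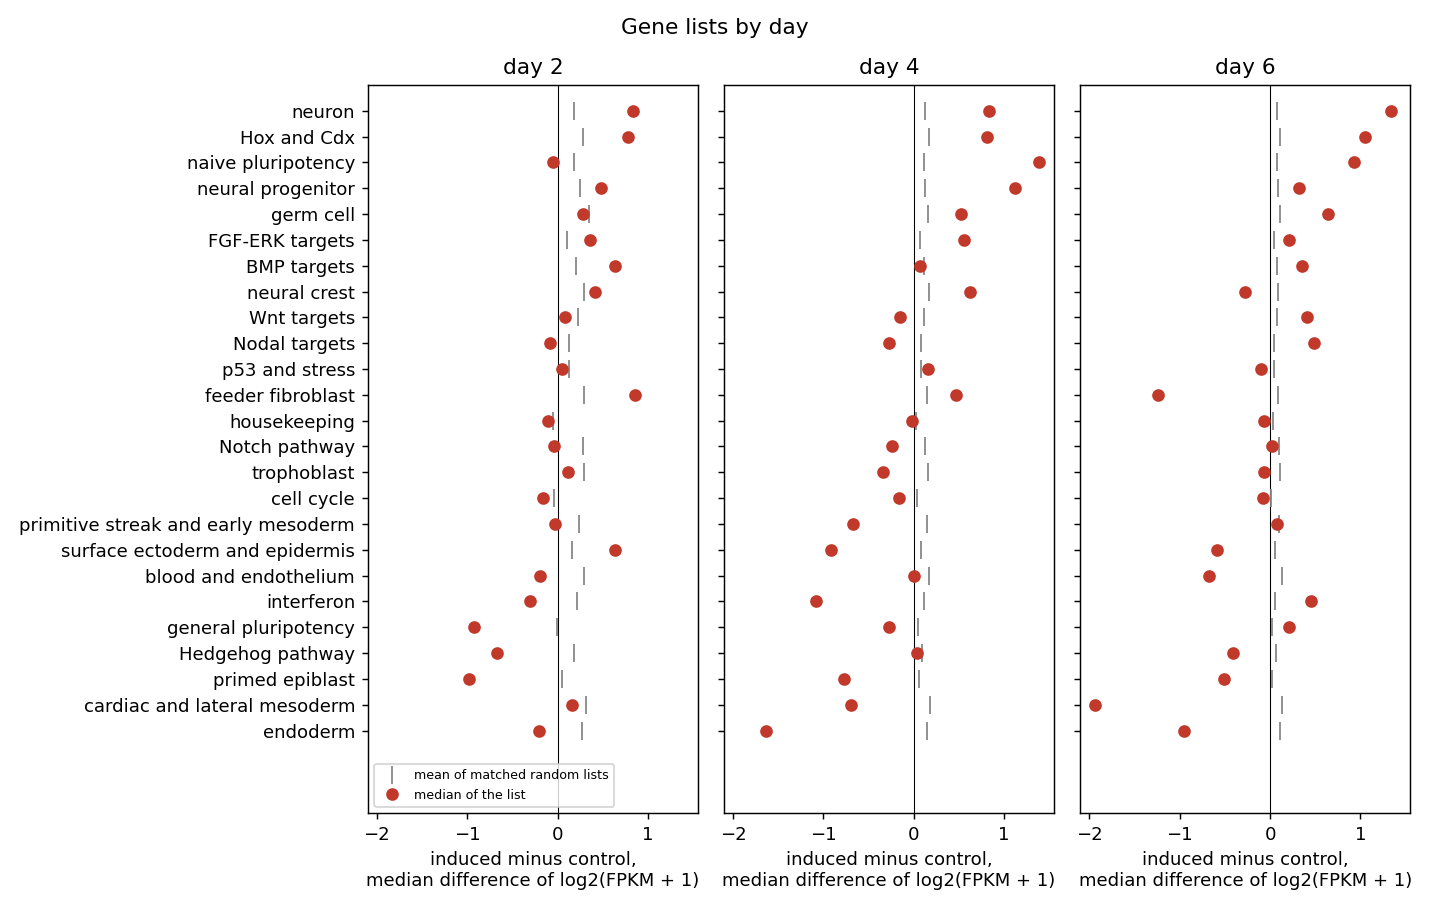
Median induced-minus-control difference of log2(FPKM + 1) for each of the 25 fixed gene lists at days 2, 4 and 6, shown as red points, with grey bars for the mean of matched random lists. The neuron list reached 1.34 at day 6, and the cardiac and lateral mesoderm list lay at -1.93 at day 6.

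The endoderm list holds many genes active in visceral endoderm. Medians over its 16 members were -0.21, -1.64 and -0.95, and 4, 9 and 7 members were at least 2-fold lower, with none 2-fold higher. Dab2 had 3.22 against 12.3, 3.69 against 45.7 and 5.82 against 38.1 FPKM, and the apolipoprotein gene Apoa1 had 0.0674 against 8.68 at day 4. The endoderm factors differed less: Gata6 by -0.13, -0.82 and -0.96 and Sox17 by -0.37, -0.92 and 0.09. Adjusted over the list alone, 5 of 16 members passed limma's test as lower, against 0 over all genes. The camera test gave an adjusted p of 7.79e-10, and an adjusted p of 0.367 with an estimated correlation. Primitive streak and early mesoderm genes had medians of -0.03, -0.67 and 0.07. At day 4, Mesp1, an early cardiovascular mesoderm factor, had 1.81 against 12.8 FPKM, Kdr, a VEGF receptor, had 0.834 against 6.97, and Pdgfra had 1.18 against 5.40. T (Brachyury) had 135 against 196 and Mixl1 43.4 against 65.7 at day 4, differences of -0.54 and -0.59. Msgn1, a paraxial mesoderm factor, had 2.69 against 0.118 at day 6.

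Of 11 measured cardiac and lateral mesoderm genes, 8 were at least 2-fold lower at day 6, and the medians were 0.16, -0.70 and -1.93. The day 2 median changed sign, to -0.02, after quantile normalisation. The camera test over the 3 days gave an adjusted p of 0.000216, and an adjusted p of 0.516 with an estimated correlation. The sarcomere genes Myl7, Tnnt2, Actc1 and Myl4 had 2.55, 2.09, 1.41 and 3.03 FPKM against 57.5, 43.8, 41.6 and 43.6 at day 6. At day 4, Myl7 and Actc1 had 1.22 and 0.963 against 8.76 and 3.99. The embryonic globins had 124 against 962 for Hbb-bh1, 22.9 against 403 for Hba-x and 3.91 against 159.7 for Hbb-y at day 6. The blood and endothelium list had medians of -0.20, 0.00 and -0.68, and Tek, an angiopoietin receptor, had 1.01 against 5.84 FPKM at day 6. The trophoblast list had medians of 0.12, -0.34 and -0.07, the first of which became -0.25 after quantile normalisation. Its members Hand1, Krt7 and 1600029D21Rik (Plet1) differed by -2.43, -0.85 and -1.12 at day 4, and Gata3 by 1.34 at day 2. In the surface ectoderm list, with medians of 0.63, -0.92 and -0.59, the simple epithelial keratins Krt8, Krt18 and Krt19 had 52.2, 36.1 and 3.85 FPKM against 197, 166 and 34.3 at day 4. The homeobox gene Dlx5 was higher on each day, with 2.05, 1.99 and 1.21.

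Of the signalling lists, BMP, Wnt, Nodal and FGF-ERK targets did not pass camera (adjusted p 0.183, 0.908, 0.581 and 0.305). Among BMP targets, Id1 had 101.4 against 35.1 FPKM, Id2 96.8 against 27.8, Id3 63.5 against 36.3 and Smad6 5.51 against 0.98 at day 2. Id2 remained higher at day 4 with 62.8 against 8.19, while Id1 and Id3 differed by 0.03 and 0.11 at day 4, and both turned negative under median ratio scaling. Msx1 had 49.4 against 18.7 and Msx2 26.8 against 13.4 at day 6, and Msx2 had 2.49 against 7.21 at day 4. The medians of the 12 BMP targets were 0.64, 0.07 and 0.35, the day 4 value becoming -0.04 under median ratio scaling, and Bmp4 itself differed by 0.40, -0.45 and 0.34. Wnt targets had medians of 0.09, -0.15 and 0.40, the first becoming -0.23 after quantile normalisation. Axin2, a feedback inhibitor of the pathway, had 4.09, 13.6 and 14.5 against 2.63, 10.5 and 7.10 FPKM. Lef1 had 3.75 against 16.8 at day 2, Notum 5.77 against 1.19 and Dkk1 12.1 against 20.96 at day 4, and Sp5 differed by 0.37, -0.21 and 0.09. Nodal targets had medians of -0.09, -0.27 and 0.48, with Lefty2 at 118 against 39.8 at day 2, and Lefty1 at 87.7 against 38.1 at day 4.

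FGF-ERK targets had medians of 0.36, 0.55 and 0.21. Egr1, an immediate early gene, had 28.9 against 4.80 at day 2 and 58.6 against 12.03 at day 4, and Fos, another, had 4.90 against 0.872 at day 2. Etv4 differed by -0.19, 0.88 and 0.97. Hedgehog pathway genes had medians of -0.68, 0.03 and -0.41, the day 4 value becoming -0.06 under median ratio scaling. At day 2, Gli1 and Ptch1, whose transcription reads out the pathway, had 5.40 and 20.9 FPKM against 17.2 and 59.9, and Shh had 1.002 against 5.39 at day 6. Notch pathway medians were -0.03, -0.24 and 0.03, the last becoming -0.03 under both scalings, and Hes5 had 5.59 against 1.16 and Dll1 5.95 against 2.29 at day 6.

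Among lists for other states, the feeder fibroblast list had medians of 0.85, 0.46 and -1.24. The stem cells had been kept on feeder cells before differentiation. Col1a2 had 80.2 against 1.76 FPKM at day 2 and 30.4 against 1.003 at day 4, whereas Tagln, Acta2 and Postn differed by -1.29, -2.28 and -2.13 at day 6. Germ cell genes had medians of 0.28, 0.52 and 0.64, the first becoming -0.15 after quantile normalisation, with Ddx4 at 2.48 against 0.618 and Nanos3 at 2.85 against 0.557 at day 6. Interferon genes had medians of -0.30, -1.08 and 0.45, with Isg15 at 2.24 against 8.78 and Usp18 at 0.972 against 5.77 at day 4. Cell cycle medians were -0.16, -0.16 and -0.08, with Ccne1 at 91.1 against 167 at day 2. The p53 and stress list had medians of 0.05, 0.15 and -0.10, the first becoming -0.10 under median ratio scaling, with Ccng1 at 150.1 against 93.6 and Atf3 at 2.95 against 0.386 at day 2. Housekeeping medians were -0.11, -0.02 and -0.06, and the mean at day 2 was 0.10. Within that list Gapdh and Pgk1 differed by -0.50 and -1.05 at day 4, and B2m had 52.7 against 12.2 at day 2, where the control library stood below all 5 others.

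The 3 days were then treated as repeats, to ask which differences were common to them. limma, with day as a block, passed 3 of 13661 genes at an adjusted p under 0.05. These were 2610203C20Rik (log2 difference 3.51, SE 0.167, adjusted p 0.0241), Snord70 (-5.62, SE 0.242, adjusted p 0.0241) and A930011O12Rik (2.79, SE 0.159, adjusted p 0.0403), a microRNA host transcript named here after its values were seen. Pou3f1, the induced gene, was not among them, with a mean difference of 3.51 and an SD of 1.10 over the days. At an unadjusted p under 0.05 there were 2870 genes, 2225 higher and 645 lower. This split depended on scaling, with 1522 higher and 1112 lower under median ratio scaling, and 1428 and 1252 after quantile normalisation. The count at an adjusted p under 0.05 was 57 without day 2, 1 without day 4 and 44 without day 6. A test of whether the difference follows the day in a straight line found 0 genes by limma, with 1052 at an unadjusted p under 0.05. Differences between days of another shape were not tested.

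By limma's camera with a preset correlation, 14 of the 25 lists passed an adjusted p of 0.05. Among them was the housekeeping list, with a 3-day median of only -0.06, so that a preset call alone is weak evidence of a change. The neuron (adjusted p 6.9e-08), Hox and Cdx (1.15e-05) and naive pluripotency (0.00305) lists were higher. The lower lists were endoderm (7.79e-10), primed epiblast (3.05e-05), blood and endothelium (0.000182), cardiac and lateral mesoderm (0.000216), primitive streak and early mesoderm (0.00385), general pluripotency (0.00305), cell cycle (0.000152), Hedgehog pathway (0.0116), housekeeping (0.0263), interferon (0.0476) and Notch pathway (0.0477). With an estimated correlation 0 of the 25 passed: the adjusted p was 0.350 for the neuron, Hox and Cdx, primed epiblast, cell cycle and blood lists, 0.367 for endoderm, 0.429 for the Hedgehog, Notch and housekeeping lists, and 0.516 for the remaining 5. limma's fry passed 0 lists, with the smallest adjusted p, 0.0904, for the neuron and the Hox and Cdx lists, and 6 lists at an unadjusted p under 0.05. At that limit camera with an estimated correlation gave 1 list, the neuron list. Leaving out a day ended some of camera's preset calls. Without day 2 the adjusted p was 0.697 for general pluripotency, 0.141 for interferon and 0.0825 for Notch. Without day 4 it was 0.480 for primitive streak, 0.620 for interferon and 0.298 for Notch. Without day 6 it was 0.0611 for naive pluripotency, 0.0653 for cardiac, 0.0591 for blood, 0.0523 for Hedgehog and 0.0559 for housekeeping. Lists that did not pass with all days passed without 1: neural progenitor at 0.0318 without day 2 and 0.00281 without day 6, BMP targets at 0.00602 without day 4, feeder fibroblast at 0.0299 without day 2 (median -0.51) and 0.0266 without day 6 (median 0.59), and surface ectoderm at 0.0499 without day 2 (median -0.95). After quantile normalisation the call ended for general pluripotency (0.0742), interferon (0.143) and housekeeping (0.156). Under median ratio scaling it ended for interferon (0.148) and Notch (0.134), and with a pseudocount of 0.1 for interferon (0.0716). The Wnt and p53 lists had 3-day medians of 0.15 and 0.07 while camera placed both on the lower side, without passing.

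The course of the control culture gives the background. Between day 2 and day 6, 2198 genes were at least 2-fold higher and 860 at least 2-fold lower, a share of 71.9% higher that became 61.2% under median ratio scaling and 52.3% after quantile normalisation. The largest positive differences were those of the embryonic globins, with Hbb-bh1 at 0.355 and 962, Hba-x at 0.0924 and 403 and Hbb-y at 0.0489 and 159.7 FPKM at days 2 and 6, and of Igf2, a fetal growth factor, at 3.56 and 1182. Among the largest negative ones, Dnmt3l, a cofactor of DNA methylation, had 190.1 and 5.39, Lefty1 163 and 6.06 and Fgf4 61.6 and 1.68 FPKM. Atp6v0c-ps2, a pseudogene, was listed at 50.02 at day 2 and at 0 in the other control libraries. Igf2 had 5.16 FPKM in induced against 3.56 in control cells at day 2, 9.26 against 33.4 at day 4 and 457 against 1182 at day 6, and Dnmt3l had 55.2 against 190.1 at day 2.

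To find where the overexpressed Oct6 sits in the genome, 7979 peaks were examined, each 133 bp wide, of which 7965 lay on assembled chromosomes. In the authors' deposited table the peak scores, which are the authors' own, ran from 7.6 to 145.6 with a median of 11.4. They move in steps of 1.27, so that the median peak holds 9 tags and precision is limited. Of the peaks on chromosomes, 21% (95% Wilson interval 20.1 to 21.9) lay within 1 kb of the start site of a protein-coding gene, 31.2% in introns, 0.552% in coding exons, 1.10% in exonic UTR and 46.1% between genes. Random positions on the same chromosomes gave 3.13%, 34.9%, 1.04%, 1.27% and 59.6%. Peaks with 16 tags or more lay near start sites in 12.5% of cases. By chromosome the density was highest on chromosome 14, with 5.33 peaks per Mb of known sequence, and chromosome 1, with 4.90, against 3.83 on chromosome 8, the next densest, and lowest on chromosome X, with 0.296 (48 peaks). Chromosome 1 beyond 110 Mb and chromosome 14 from 60 to 120 Mb, bounds set after the distribution was seen, held 7.48 and 8.75 peaks of 8 or more tags per Mb, against 2.85 in the other autosomal sequence.

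**Figure D3:**
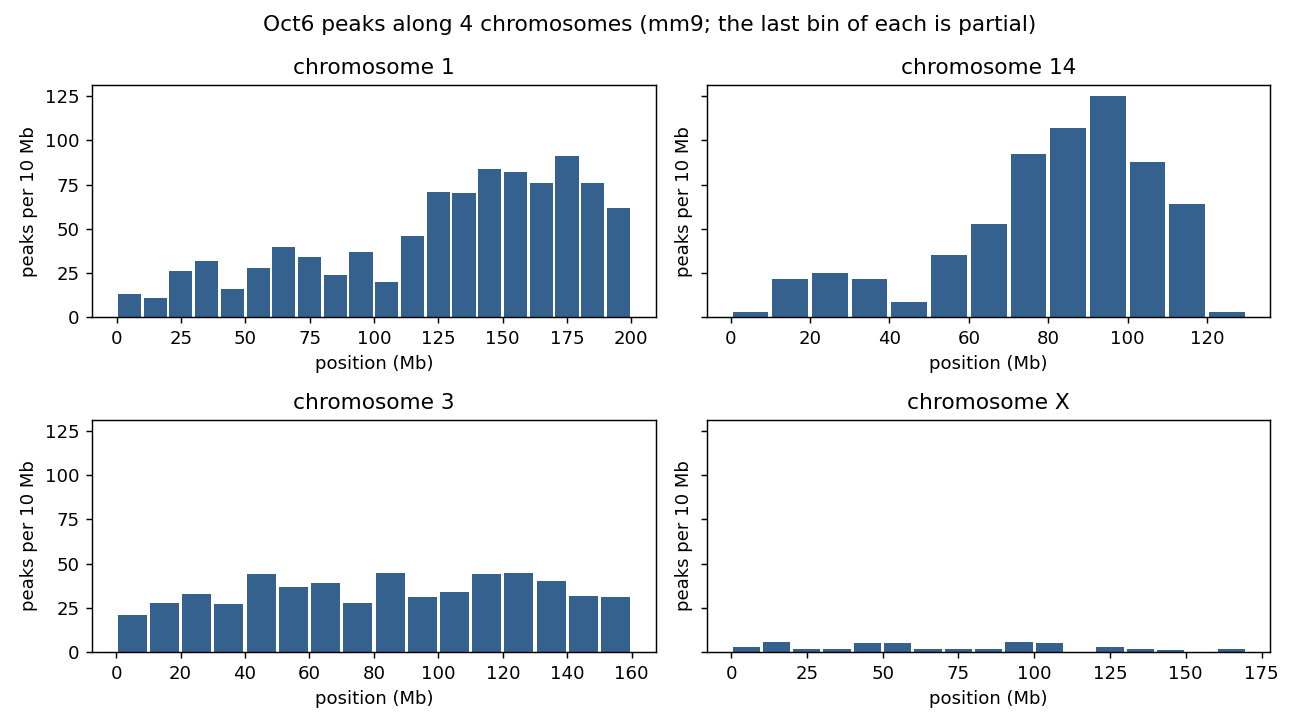
Number of Oct6 peaks per 10 Mb against position in Mb (mm9) on chromosomes 1, 14, 3 and X, with 1 bar per bin. Bars are taller on chromosome 1 beyond 110 Mb and on chromosome 14 from 60 to 120 Mb, and chromosome X holds 48 peaks in all.

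The 7-base words most enriched in peaks over their flanks were ATGCATA (13.7% of peaks, 2.64% of flanks) and ATGCATG (12.4% and 2.5%). The palindrome ATGCAT, which holds the POU core site ATGC on both strands, was present in 19.5% of peaks (18.7 to 20.4), against 5.07% of flanks and 4.40% of random positions. The canonical octamer ATGCAAAT was present in 4.19% (3.77 to 4.66) against 1.27% of flanks. A longer palindromic POU dimer site, ATGCATATGCAT, occurred in 43 peaks, or 0.540%, against 0.00628% of flanks. The share with ATGCAT increased with the score, from 15.7% (14.5 to 16.9) of the 3289 peaks with 8 tags or fewer to 52.7% (46.6 to 58.6) of the 264 peaks with 16 tags or more. Words with an ETS core, such as CCGGAAG (2.35% against 0.647%), were also enriched.

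**Figure D4:**
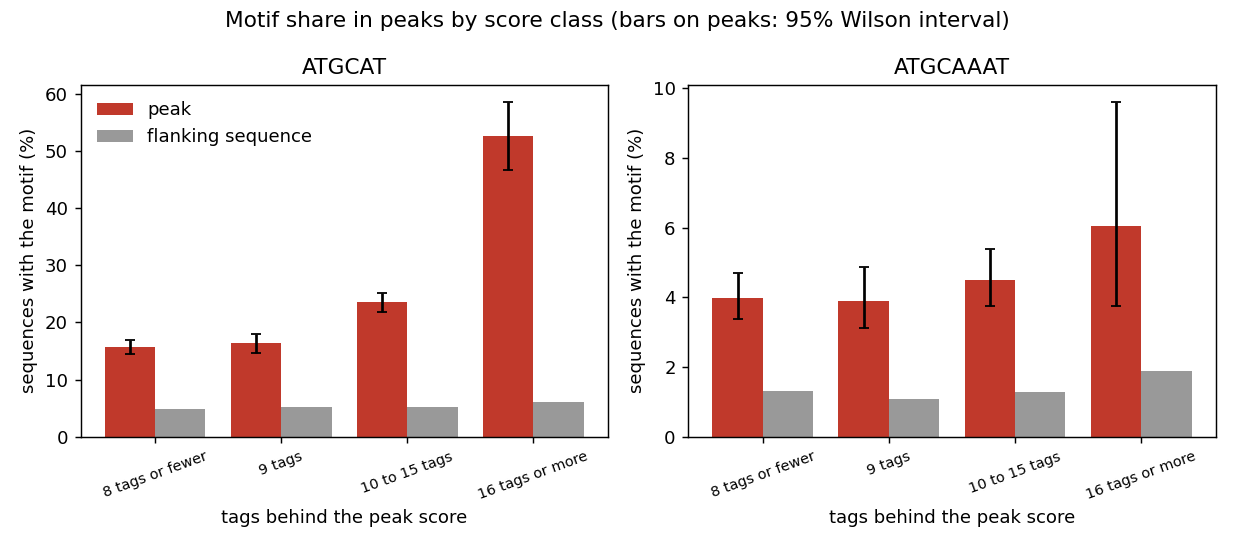
Percentage of peaks and of flanking sequences that hold ATGCAT or ATGCAAAT, by the number of tags behind the score, with 95% Wilson intervals on the peaks. ATGCAT was present in 52.7% of peaks with 16 tags or more and in 15.7% of those with 8 tags or fewer.

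In the authors' deposited table the peak of highest score, 145.6, lay on chromosome 11 at 108873166 to 108873298 (mm9), between genes and 91569 bp from the start site of Axin2. The next, with scores of 113.9 and 105.1 in the authors' deposited table, lay on chromosome 6 at 3151433 to 3151565, nearest to Samd9l at 198072 bp, and on chromosome 5 at 147072564 to 147072696, in an intron and nearest to the start of Cdk8. The others among the 10 highest lay nearest to Limd1, in an exonic UTR, to 2610005L07Rik, 9 bp from its start and outside protein-coding genes, to Fam38b, and in introns nearest to Filip1l, Klf12, Clip2 and Kpna1. ATGCAT was present in 2 of these 10, the peaks near Fam38b and Klf12, against 52.7% of all peaks with 16 tags or more, and the octamer in 0. The rise of the ATGCAT share with the score thus did not extend to these 10, and their ChIP and input signal was not examined.

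A peak lay within 10 kb of 17.8% (17.2 to 18.5) of the start sites of 13399 expressed genes, against 6.16% for random positions. Pou3f1 had 2 such peaks, the nearer on chromosome 4 at 124334389 to 124334521, 441 bp from its start. Of the genes at least 2-fold higher at day 4, 172 of 752 (22.9%, 20 to 26) had a peak within 10 kb, above all of 10000 random gene sets matched on mean expression, which averaged 15.1%. Of the lower genes 22 of 260 (8.46%, 5.65 to 12.5) had one, at percentile 0.045 of sets that averaged 15.7%. Of the remaining genes 18.5% had one. They were not matched on expression, and within 2 kb their share was 13.4%, against 12.4% of the higher genes. Higher genes of days 2 and 6 had shares of 22.6% and 22.5%, above all of their random sets. Of the lower genes of day 2, 32 of 218 had one (14.7%, percentile 20.3, random mean 16.7%), inside the central range of the random sets, and of those of day 6, 21 of 255 (8.24%, percentile 0.98, random mean 12.9%). Among genes 2-fold higher on all 3 days the share was 42 of 140, or 30.0%, and among the 10 lower on all days it was 0. When peaks were limited to the 3989 of highest score, lower genes stood at 5.38% and percentile 6.16, inside the central range of the random sets.

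Named genes with a near peak included Lmo1, with a peak 224 bp from its start (chromosome 7, 116313980 to 116314112), C1ql2 at 154 bp, Ncam1 at 92 bp, Id2 at 262 bp, Hoxb4 at 2642 bp in an intron, Col1a2 at 2982 bp in an intron, Sox2 at 3605 bp, Nmu at 4327 bp, Sox21 at 6554 bp, Zfp521 at 7677 bp in an intron and Zic1 at 9975 bp. Ptch1, lower at day 2, had one at 101 bp. The nearest peak to Scin was 88503 bp away. C1ql2 and Sox21 lie in the segments of chromosomes 1 and 14 with denser peaks, where a near peak is more likely. Shares of genes and lists with a peak were not recounted without these segments. By list, 6 of 11 FGF-ERK targets had a peak within 10 kb (Spry2, Spry4, Dusp6, Etv5, Spred1 and Ier3), at percentile 98.7 of matched random lists, and 5 of 20 neuron genes, at percentile 91.0. None of 16 endoderm, 10 primed epiblast, 14 Wnt target or 11 cardiac and lateral mesoderm genes had one, at percentiles 3.27, 4.11, 4.11 and 9.84. Of 19 neural progenitor genes, 3 had a peak, at percentile 58.8.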

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

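The tests of a copy number gain in the induced arm alone and of gene density, the share of lower genes among the 170 that could lie below control day 2, and the share after median ratio scaling as a test of scaling, were chosen after the result was seen. With 1 library per arm and day, opposite directions on different days are differences between libraries that were not tested, and limma's test of a day trend passed 0 genes, with 1052 at an unadjusted p under 0.05.

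The directions differed between days for 8 named genes, each at least 2-fold higher in induced cells on 1 day and at least 2-fold lower on another. For Gm9846 the span from the lowest to the highest day was 9.64, for Snord58b 7.44 and for Amd1 6.67, all short RNAs or genes with close copies. Myl4 (span 4.66, from 1.19 at day 2 to -3.47 at day 6), Postn (4.66, from 2.53 at day 4 to -2.13 at day 6), Krt19 (4.24, from 1.38 at day 2 to -2.86 at day 4), Acta2 (3.62, from 1.35 at day 2 to -2.28 at day 6) and Tagln (3.58, from 2.29 at day 2 to -1.29 at day 6) are contractile, matrix or epithelial genes. Medians of 6 lists passed from 1 tail of the matched random lists to the other between days. The spans were 2.09 for feeder fibroblast, 1.55 for surface ectoderm and epidermis, 1.53 for interferon, 1.13 for general pluripotency, 0.76 for Nodal targets and 0.56 for Wnt targets.

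Peaks were unevenly spread: chromosome 1 beyond 110 Mb held 7.48 peaks of 8 or more tags per Mb and chromosome 14 from 60 to 120 Mb held 8.75, which is 2.62 and 3.07 times the density of the other autosomal sequence, while chromosome X held 0.0988 times that density. A higher density of genes does not account for it, since start sites per Mb were 0.798 and 0.468 times those elsewhere. A gain carried by the induced cells alone is argued against by the RNA, where genes of the segments exceeded other autosomal genes by at most 0.0687 in median log2 difference (day 2, bootstrap interval 0.01 to 0.13), where 0.3 or more was predicted. A copy number gain of 3 against 2 in the cells of the ChIP is a candidate explanation, whether or not the control arm shared it. Tags in the segments were thinned to 2 of 3. The density then fell to 0.764 (0.660 to 0.881) and 0.845 (0.713 to 0.994) times that elsewhere. Both lay inside the limits set before the test, although both intervals reach below the lower limit of 0.75. Since the median peak held 9 tags and peaks were kept at 8 or more, thinning lowers the density whatever the cause. The bounds were also drawn from these same peaks, so that the test cannot decide. Thinning autosomal peaks to 1 of 2 tags predicted the density of chromosome X within a ratio of 1.31 (0.961 to 1.74); the copy number itself was not measured, and no biological explanation was tested.

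Of the genes changed at day 2, 84.2% were higher in induced cells. Counting noise of weak genes is argued against, since with a floor of 5 FPKM the share was 81.8%. Scaling between the 2 libraries and a true excess cannot be told apart: the share was 75.2% after median ratio scaling, which leaves most of the excess, and after quantile normalisation, which makes all libraries' distributions equal, it was 61.1%, between the 40 to 60% that scaling as the whole cause predicted and the 70% above which it would have been excluded, and no spike-in gives an outside scale. The control library of day 2 had the fewest genes at 1 FPKM or more, 11434 against 11833 to 12457 in the others.

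Genes lower at day 4 may reflect a slower course of differentiation in the induced culture. For these genes 88.1% had an induced day 4 level no more than 2-fold below that of control day 2, but 98 of the 268 stood too low at control day 2 to lie 2-fold below it (of the other 170, 81.2% did not), and a block of single lineages would also give a high share, so that it decides nothing. Across genes, the day 4 effect did not run against the control change from day 2 to day 6, with which it shares no library (Spearman rho 0.108, where below -0.2 was predicted). Of the genes higher at day 4, 38.1% (34.7 to 41.6) stood more than 2-fold above each of the 3 control libraries, against the prediction of fewer than 20%. For the higher genes this argues against a slower course as the whole cause, although the share did not reach the limit set beforehand for excluding it. For the lower genes, and for a part of the higher ones, a slower course and an effect of Oct6 on lineage choice cannot be told apart here. Day 0 and the days between the samplings were not measured, and the induced arm is 1 culture per day. An effect of doxycycline itself is not separated from either if control cells received none. Nor is a difference between cell lines, if the arms are of different lines.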

How the results depend on the processing

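The counts without small RNA, predicted and pseudogene symbols, and named genes under median ratio scaling, were chosen after seeing the data. Of 8 alternatives each, 4 kept the count of changed genes within 1.5 times at days 2, 4 and 6. Among these, no floor could change nothing, since a difference of 1 in log2(FPKM + 1) already requires an FPKM of 1. At days 2, 4 and 6 the counts were 2333, 1623 and 1144 with a pseudocount of 0.1, 957, 578 and 349 with a floor of 5 FPKM, 3647, 2491 and 1635 at 1.5-fold, and 269, 199 and 125 at 4-fold, where fewer or more genes can qualify by construction. The control change from day 2 to day 6 stayed within 1.5 times in all 6 alternatives, of which no floor again could change nothing. Genes passing limma over the 3 days numbered 3, against 1 with a pseudocount of 0.1, 0 without a floor (3331 at an unadjusted p under 0.05), 1 with a floor of 5 FPKM and 17 after quantile normalisation; leaving out a day gave 1 to 57, and without small RNA, predicted and pseudogene symbols there were 6. The cause was not tested. All 3 genes passed again under median ratio scaling, quantile normalisation and eBayes without trend, and 2 of them without the day block. limma's day trend count was 0 under all 7 alternatives, with 793 to 1400 at an unadjusted p under 0.05. Lists passing camera numbered 11 to 14 under the alternatives, except for 0 with an estimated correlation, for which the cause was not tested. The share of start sites with a peak was 8.84% with the 3989 peaks of highest score, 12.4% at 2 kb and 38.9% at 50 kb, and the shares of higher and lower genes were 11.8% and 5.38%, 12.4% and 1.92%, and 47.1% and 27.7%, since fewer peaks or another window were counted. Of 444 values of named genes by day, 23 changed sign under a scaling or pseudocount, all below 0.30 in size. Of 148 named genes, the mean difference moved by more than its SD over the days in 30 with a pseudocount of 0.1, 4 after quantile normalisation and 1 under median ratio scaling. The day block pairs the arms within each day. No paired analysis was possible by replicate number because each group holds 1 library. Depth limits the ChIP, with 9 tags behind the median peak.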

Other observations

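The split counts below were chosen after the model results had been seen, as were the correlations between days. Across 13661 genes, which are not independent replicates, the day 2 difference and the control change from day 4 to day 6, which share no library, had a Spearman rho of 0.357 (Pearson r 0.285). For the day 6 difference and the control change from day 2 to day 4 it was 0.0341 (Pearson r -0.0836). Effects on neighbouring days were related across genes, with rho of 0.473 for days 2 and 4, 0.472 for days 4 and 6, and 0.259 for days 2 and 6. The control libraries of each day differ, so these 3 values share no control.

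Each arm changed by a different amount between days. In control cells 3058 genes differed at least 2-fold between days 2 and 6, and in induced cells 1645 did. Between days 2 and 4 the numbers were 1758 and 652. The difference between arms was not tested, and the induced library at day 2 already differed from control at 1453 genes.

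For the genes passing limma over the 3 days, 3 against 3 libraries allow only 10 splits, too few for a share under 0.05: the real split gave 3 genes and the highest of the others 0. Of the 10 splits, 4 put 1 library of each day in each group, the real one among them, and in the other 6 only 1 day enters the contrast, so that they say little. For the day trend the 10 splits are as few, the real split gave 0 genes by limma, with 1052 at an unadjusted p under 0.05, and the highest of the others 4.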
